A study of Drosophila melanogaster with 2 samples.

How the data were processed

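The samples were 2 libraries of sorted gut nuclei from Drosophila melanogaster, 1 per group (Homeostasis and Recovery), each from 70 guts; nuclei were sorted before the libraries were made, per the labels' protocols. The authors deposited a matrix of UMI counts for 16495 genes and 8073 barcodes, and a table that gives each barcode its library and 1 of 14 cluster names. Cell Ranger 3.1.0 made the counts, per the submitters' processing notes; the genome build, the annotation and the method of clustering are not given in the sources used here, so no coordinates are printed and genes are named by the symbols of the matrix. All values were whole numbers, and 0 barcodes lacked an annotation. The lowest total per nucleus was 500 UMIs in Homeostasis and 475 in Recovery. CPM values (counts scaled to a common total), ratios and shares were computed here from the deposited counts.

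Cell classes were taken from the authors' cluster names: enterocytes are the 7 clusters whose names hold EC with a regional prefix (aEC1 to aEC3, mEC, pEC1 to pEC3), progenitors are ISC/EB, and EE was used as annotated. Each cluster's 10 leading genes by fold were compared with 16 lists of cell type markers. LFC,Cu,Fe had 2 visceral muscle markers and none of its own, and is compared as a cluster only. EE had 1 marker of its own and 1 of fat body, mEC is led by the middle midgut marker lab, and proEC, whose abbreviation the labels do not explain, has no marker among its leading genes, although stem cell and enteroblast markers are high in it. Genes among a cluster's 10 leading genes are not read as differences within that class.

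With 1 library per group there is no test across samples. UMI counts were summed per class and library and divided by the class total to give CPM. Each ratio has an exact conditional 95% interval and each share an exact Clopper-Pearson 95% interval, which cover counting error only. A count of 0 was set to a floor of 3 counts over the class for a bound on the fold. For each of 28 gene lists, the median log2 ratio over members with at least 20 UMIs in both libraries together (members at 0 entered at the floor) was placed among 10000 random lists of the same size matched in 20 bins of expression. Its interval comes from 1000 Poisson redraws of the counts with 0.5 added. Classes with at least 50 nuclei in each library were compared, which leaves 6 of the 7 enterocyte clusters. The lists, the markers and the rule for named genes were fixed before the data were examined. Of 393 listed symbols 7 were matched through a synonym and 1 (Pept2) was not matched.

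Genes were named by this rule: among genes with at least 50 UMIs in both libraries together and at least 20 CPM in either, leaving out mitochondrial and ribosomal RNA genes, those whose interval bound nearest to 1 was most extreme, 12 each way in enterocytes, 8 in ISC/EB, 6 in EE and the whole libraries and 2 in every other class, with a limit on genes known only by a number. Added to these were all receptor, acetylcholine and innexin genes with at least 20 UMIs, and from other lists up to 2 members each way with at least 50 UMIs. Sub-clusters, heat shock nuclei, lncRNA:CR34335 by cluster and the nuclei behind each gene were looked at after the values were seen.

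Shares of nuclei with a UMI were also computed after thinning each nucleus to 899 UMIs, the 20th percentile of all nuclei. For heat shock nuclei the thinned depth was 500 UMIs, and 67 shallower nuclei, all in Recovery, were left out. Scrublet's automatic threshold marked 0 Homeostasis nuclei and 1 Recovery nucleus as doublets. The sources used here do not say whether doublets were removed before deposit, so doublets may remain in the data. The 5% of nuclei with the highest scores (190 and 193) were left out as an added alternative. For a rebuilt set of classes, scanpy was run on counts scaled to 10000 per nucleus with 2000 variable genes, 40 principal components, 15 neighbours and Leiden resolution 1, and clusters were named from the markers; the naming rule was revised after its first result was seen, and the rebuilt classes overlap the annotated ones only in part. Sub-clusters of 4 annotated clusters used 1500 genes, 20 components, 10 neighbours and resolution 0.6. Alternatives also covered TMM factors (edgeR) and DESeq2 size factors on the summed counts, filters on genes and nuclei, the weight of each nucleus, the most abundant 20 genes left out of the total, and the mix of enterocyte clusters. The median ratio without the 5 richest nuclei of each gene leaves them out of the library with the higher CPM, a definition set after a first version was seen.

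The steps were tested on simulated enterocyte counts, drawn as Poisson counts around means shared by both libraries except for the changed genes. These counts hold only the error that the intervals assume, with no clumping of UMIs in single nuclei and no variation between libraries. The results therefore check the calculation and not how reliable the differences in the real libraries are. Over 7371 genes, the interval lay on the right side of 1 for 56 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold, and held 1 for 95.7% of unchanged genes. A list of 20 genes raised 2-fold had a median log2 ratio of 0.99 at percentile 100, an unchanged list -0.02 at percentile 23.6, and 24 of 24 named genes were truly changed. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.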

Results

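Single-nucleus RNA sequencing was used to profile guts of adult Drosophila melanogaster females of the wild-type strain Oregon R, kept at 29 °C. Flies of the Homeostasis group ate standard food for 6 days. Flies of the Recovery group ate food containing 2% dextran sulfate sodium (DSS), a polymer that injures the gut lining, for 4 days and then standard food for 2 days. Each group was 1 library made from sorted nuclei of 70 pooled guts, so the differences given here have no replicate check. The Homeostasis library held 3820 nuclei and 11886984 unique molecular identifiers (UMIs, each standing for 1 captured transcript), with a median of 2736.5 UMIs and 1157.5 genes per nucleus. The Recovery library held 4253 nuclei and 10087296 UMIs, with medians of 1775 UMIs and 833 genes. Intervals are 95% intervals and cover counting error only.

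The comparison of both libraries addresses the state of the gut epithelium after injury, with attention to acetylcholine signalling from neurons, gap junctions and calcium, the subjects of the series title. Enterocytes, the cells that digest and absorb food, made up 67.3% (65.7 to 68.7) of the Homeostasis nuclei and 46.5% (45 to 48) of the Recovery nuclei. As a share of all nuclei, the cluster annotated pEC1 was 2.41-fold lower in Recovery (15.8% against 6.56%), aEC1 was at 8.25% against 5.53%, aEC2 at 4.84% against 2.45% and pEC2 at 9.45% against 7.81%, while pEC3 was 1.62-fold higher (8.90% against 14.4%) and mEC was at 7.70% against 8.72%. As a share of enterocytes, pEC1 was again lower (23.5% against 14.1%) and aEC2 too (7.20% against 5.26%), aEC1 was about level (12.3% against 11.9%), and pEC2 (14.1% against 16.8%), mEC (11.4% against 18.8%) and pEC3 (13.2% against 31.0%) were higher. Posterior enterocyte markers stood above the other clusters in pEC1 (median log2 1.34) but below them in pEC3 (-1.49), so the names are used for clusters and not for regions. The largest gap in share of all nuclei was in the cluster annotated aEC3, with 471 nuclei (12.3%) in Homeostasis and 43 (1.01%) in Recovery. Since nearly all of aEC3 came from 1 library it may mark that library, and without it the difference in enterocyte share was -9.42 percentage points in place of -20.7 (-22.9 to -18.6). A class rebuilt from clusters made for this work gave -11.1 points, but it held only 58.6% of the annotated enterocytes, and 77.6% of its nuclei were annotated so. The sorting of nuclei can set shares. Depth can too, but the lower Recovery median over all nuclei may itself follow from the smaller share of deep enterocyte nuclei. Within classes median depths were closer, at 3610 and 3324.5 UMIs in enterocytes, 673 and 693 in ISC/EB and 854 and 877 in EE. In LFC,Cu,Fe they were 1198 and 1025.5.

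**Figure D1:**
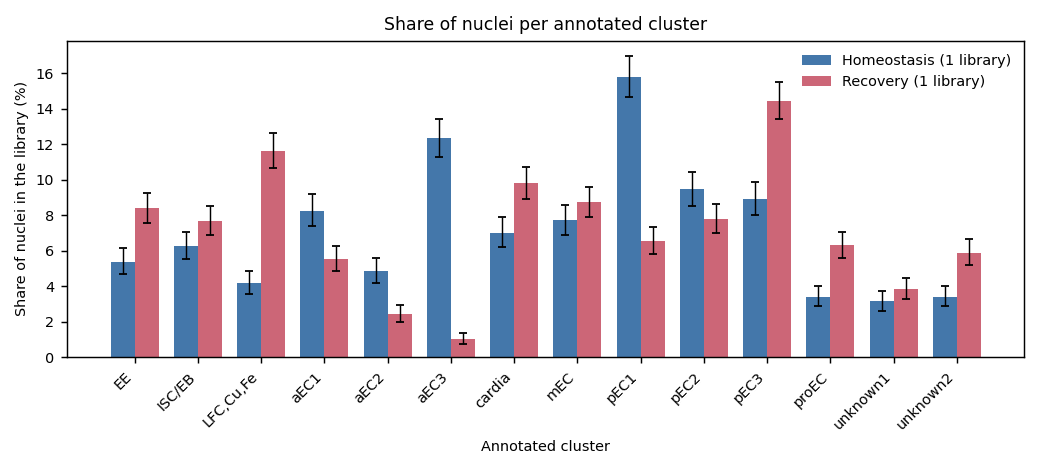
Bars give the share of each library's nuclei (%) in each of the 14 annotated clusters, for 1 Homeostasis library of 3820 nuclei and 1 Recovery library of 4253 nuclei, with exact 95% binomial intervals that cover counting error only. The aEC3 bar is 12.3% in Homeostasis and 1.01% in Recovery, and the pEC3 bar is 8.90% and 14.4%.

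Intestinal stem cells and enteroblasts (ISC/EB), the progenitors that renew the epithelium, made up 6.26% (5.51 to 7.07) of Homeostasis and 7.69% (6.91 to 8.53) of Recovery nuclei, a difference of 1.43 percentage points (0.302 to 2.56). The lowest total per nucleus was 500 UMIs in Homeostasis and 475 in Recovery. Of the 67 Recovery nuclei under 500 UMIs, 18 were ISC/EB and 18 EE. At a minimum of 500 ISC/EB held 309 of 4186 Recovery nuclei against 239 of 3820, a smaller difference. Shares add up to the whole, so a lower enterocyte share raises the others, and every cluster outside the enterocytes had a larger share in Recovery. Among nuclei outside the enterocytes, ISC/EB held 239 of 1251 in Homeostasis and 327 of 2275 in Recovery, a smaller part in Recovery. The progenitor class of the rebuilt clusters, of which 52.0% was annotated ISC/EB and 30.1% proEC, differed by 3.22 points. Of the sub-clusters of ISC/EB, the largest, led by genes that include the Notch targets E(spl)mbeta-HLH and E(spl)malpha-BFM, held 84 Homeostasis and 143 Recovery nuclei. The sub-cluster led by the Notch ligand Dl, a stem cell marker, held 91 Homeostasis and 75 Recovery nuclei, whereas the sub-cluster led by genes that include the cytokine upd3 and the EGFR ligand vn held 36 and 62, and the others 22 and 43 and 6 and 4. The cluster annotated proEC held 130 Homeostasis nuclei (3.403%) and 268 Recovery nuclei (6.301%). Stem cell and enteroblast markers were as far above the other clusters there (median log2 3.97) as in ISC/EB (3.72), but none is among its 10 leading genes. The first of these are yl, dhd and CycB, and all 202 Homeostasis UMIs of dhd and all 54 of CycB lay in 2 nuclei, while Recovery had 0 and 1. It was kept apart from ISC/EB because its name is not explained, and with it added the progenitor difference was 4.33 points.

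The cluster annotated EE, for enteroendocrine cells that secrete peptide hormones, held 5.37% of Homeostasis and 8.39% of Recovery nuclei, a difference of 3.03 points (1.91 to 4.14). Among nuclei outside the enterocytes, EE held 205 of 1251 and 357 of 2275, which is not a larger part in Recovery. Its leading genes hold 1 enteroendocrine marker (AstA) and 1 fat body marker (apolpp), and only 29 Homeostasis and 43 Recovery nuclei fell in its sub-cluster led by enteroendocrine markers, at 0.759% (0.509 to 1.09) and 1.01% (0.733 to 1.36). The rebuilt class, which held 13.2% of the nuclei annotated EE, differed by 0.144 points. The cluster annotated LFC,Cu,Fe held 4.16% and 11.6%; visceral muscle markers (tn, Act57B) were among its leading genes, so it is treated as a cluster and not as a class. The cluster annotated cardia, after the valve between foregut and midgut, held 7.02% and 9.80%. Cardia and foregut markers stood barely above the other clusters there (median log2 0.065) and none is among its leading genes, so the name is used for the cluster only. The clusters annotated unknown1 and unknown2 held 3.14% against 3.81% and 3.403% against 5.878%.

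In enterocytes, genes of the heat shock response stood furthest above Homeostasis in Recovery together with antimicrobial peptides. Of 10 measured heat shock genes 9 were higher, with a median log2 ratio of 4.19 (3.29 to 4.30), at percentile 100 of 10000 random lists matched on expression. Hsp26, a small heat shock protein, had 42 UMIs in Homeostasis and 713 in Recovery and was 24.0-fold higher in CPM, the counts scaled to a common total (17.6 to 33.6). Hsp27 was 14.5-fold higher (12.04 to 17.65), Hsp68 36.8-fold (16.5 to 102), Hsp70Ab 27.5-fold (14.2 to 61.2) and Hsp83, the Hsp90 of the fly, 7.31-fold (6.30 to 8.50). The transcription factor of the response, Hsf, was 1.19-fold lower (1.09 to 1.31), and the co-chaperone stv 1.17-fold higher (1.14 to 1.21). The transcripts were uneven between nuclei: 153 of 1978 Recovery enterocyte nuclei (7.74%, 6.596 to 9.001) and 6 of 2569 Homeostasis nuclei (0.234%) held at least 5 UMIs of 11 inducible heat shock genes, and these Recovery nuclei carried 86.3% of such UMIs. Without them the median log2 ratio was 2.01.

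**Figure D2:**
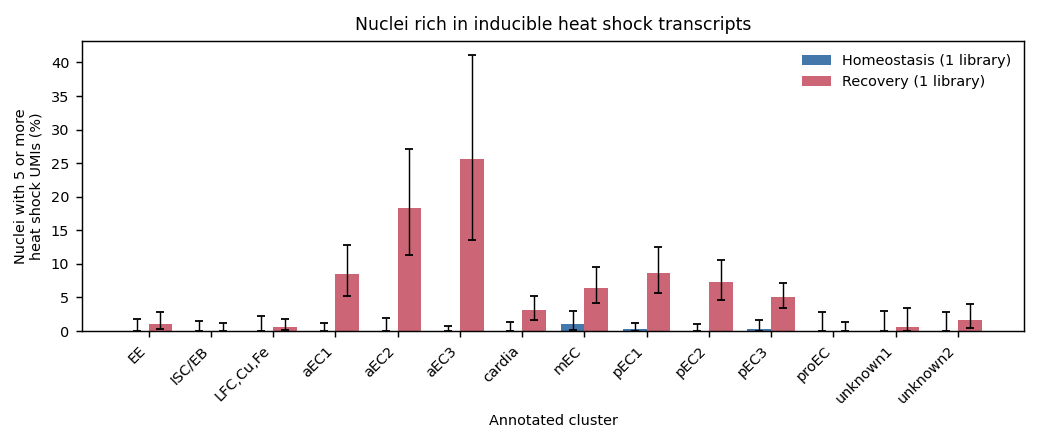
Bars give the share of nuclei (%) with at least 5 UMIs of the 11 inducible heat shock genes in each annotated cluster of the 1 Homeostasis and the 1 Recovery library, with exact 95% binomial intervals that cover counting error only. The Recovery share is 25.6% in aEC3 (43 nuclei) and 18.3% in aEC2, and no nucleus of ISC/EB or proEC passes the minimum.

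By cluster, Hsp26 was 41.0-fold higher in aEC1 (13.7 to 202), 37.9-fold in pEC3 (10.3 to 316), 16.7-fold in pEC1 (9.30 to 32.5), 14.6-fold in pEC2 (6.41 to 40.8) and 6.73-fold in mEC (3.98 to 12.1). In aEC2 it had 0 UMIs in Homeostasis and 121 in Recovery, which makes it at least 82.4-fold higher. In ISC/EB the 11 inducible genes had 1 UMI in Homeostasis and 18 in Recovery, and with nuclei thinned to 500 UMIs 0.418% (0.0106 to 2.31) and 2.59% (1.12 to 5.04) of them held such a UMI. Only 3 genes of the heat shock list reached 20 UMIs there, too few inducible ones for the list's median to describe the response.

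All 6 measured antimicrobial peptides, secreted products of innate immunity, were higher in Recovery enterocytes, with a median log2 ratio of 4.69 (4.11 to 6.06; percentile 100). DptA had 0 UMIs in Homeostasis and 78 in Recovery, at least 36.8-fold higher. Drs was 27.7-fold higher (17.3 to 47.3), AttD 1.55-fold (0.926 to 2.61). Few nuclei carried these transcripts, as 5 Recovery nuclei held 286 of the 352 Drs UMIs and without them Drs was 5.19-fold higher (3.05 to 9.29). The list's median was 2.88 without the 5 richest nuclei of each gene, with AttD at a ratio of 0.411 (0.172 to 0.885), and 3.26 without the 5% of nuclei with the highest doublet scores. In the same class the fat body genes Yp1 and FASN1 were 5.66-fold (3.715 to 8.90) and 1.10-fold (1.03 to 1.18) higher, and Drs and AttD are among the genes that lead a rebuilt cluster of which 89.9% was annotated LFC,Cu,Fe. By contrast, 10 of 13 genes of the IMD pathway, which senses bacterial peptidoglycan and controls these peptides, were lower, with a median of -0.23 (-0.27 to -0.08) that lay at percentile 21.5. PGRP-SC2, an amidase that degrades peptidoglycan, was 1.93-fold lower (1.53 to 2.46), and PGRP-LB was 1.09-fold higher (1.03 to 1.15).

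The median log2 ratio over all 8653 genes measured in enterocytes was -0.16 with CPM and -0.0079 with TMM factors, so a list near -0.16 did not stand apart from other genes and medians from -0.15 to 0 lie above 0 with TMM factors. Folds of single genes carry the same shift. JAK-STAT genes, which carry the cytokine signal of damaged gut cells, had a median of 0.47 (0.38 to 0.55; percentile 99.8), with 4 of 6 higher. Socs36E, a feedback target of the pathway, was 2.47-fold higher (2.39 to 2.57) at 1122 CPM against 453.7, and higher in 6 of 6 enterocyte clusters compared. The cytokine upd3 was 1.91-fold higher (1.55 to 2.35), but 1.21-fold with the same mix of clusters in both libraries; hop, the kinase, was 1.07-fold lower (0.879 to 1.29). Of 14 EGFR pathway genes 11 were higher, with a median of 0.10 (0.04 to 0.17; percentile 97.0) that became -0.0135 without the 5 richest nuclei of each gene. The median of all genes was -0.115 in that setting. Egfr was 1.96-fold higher (1.70 to 2.27) and rho, which releases its ligands, 3.77-fold higher (2.80 to 5.13). Both rho and upd3 are among the leading genes of a rebuilt cluster with 127 Homeostasis and 351 Recovery nuclei. Of that cluster 45.4% was annotated mEC, and its closest marker list was stem cell and enteroblast (median log2 0.85). The folds of rho and upd3 may therefore reflect which nuclei fell among the enterocytes, which was not tested. The list of JNK and TNF genes, a stress and wound pathway, went both ways, with 7 higher and 6 lower and a median of 0.27 (-0.07 to 0.31; percentile 99.6). The matrix protease Mmp2 was 3.21-fold higher (2.93 to 3.52) and the TNF ligand egr 1.46-fold (1.13 to 1.90), while the kinases Tak1 and hep were 1.46-fold (1.33 to 1.60) and 1.41-fold (1.32 to 1.51) lower. Mmp2 was 2.06-fold higher with the same mix of clusters. For Notch, 7 of 9 genes were higher with a median of 0.23 (0.01 to 0.49; percentile 98.6), including N itself at 1.62-fold (1.37 to 1.93), but the median was -0.066 without aEC3 and mEC. With those clusters left out the median of all genes was -0.16.

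Most genes of digestion were lower over all enterocytes, and less so within each cluster. Of 50 measured digestive enzymes 44 were lower in Recovery enterocytes, with a median log2 ratio of -0.41 (-0.46 to -0.35), below all 10000 matched random lists. The maltase Mal-A5 was 4.31-fold lower (2.19 to 9.43) and the protease Ser8 2.48-fold lower (2.03 to 3.06). The amylase Amy-p was 1.24-fold higher (1.19 to 1.29), in 6 of 6 clusters, and Mal-A2 was 1.22-fold higher (1.01 to 1.47). With the same mix of clusters the list's median was -0.24, and within clusters it was -0.25 in aEC1 (-0.40 to -0.17), -0.19 in pEC1 (-0.34 to -0.13), -0.10 in aEC2 (-0.24 to 0.02), -0.02 in pEC2 (-0.10 to 0.17), -0.01 in mEC (-0.14 to 0.17) and 0.01 in pEC3 (-0.09 to 0.11). Summed over the list, these transcripts made up 1.36% of enterocyte UMIs in Homeostasis and 1.22% in Recovery, against 1.58% and 1.66% over the whole libraries. They were 2.67% and 2.64% of the UMIs of ISC/EB, at 19.4 and 19.8 per nucleus against 54.1 and 44.6 in enterocytes. Subunits of the vacuolar ATPase, the proton pump, were lower in 13 of 16 cases with a median of -0.38 (-0.41 to -0.29; percentile 0.22), such as Vha36-1 at 1.66-fold (1.43 to 1.94) and Vha14-1 at 1.52-fold (1.32 to 1.76) lower. Oxidative stress and detoxification genes had a median of -0.31 (-0.43 to -0.17; percentile 6.22) with 15 of 19 lower; the cytochrome P450 genes Cyp12d1-p and Cyp6a8 were 11.1-fold (4.90 to 30.9) and 3.71-fold (2.45 to 5.83) lower, and the catalase Cat was 1.24-fold higher (1.18 to 1.29). Cell cycle genes had a median of -0.41 (-0.66 to -0.22; percentile 8.98), with tum 1.66-fold lower (1.36 to 2.04) and E2f1 1.23-fold lower (1.18 to 1.27).

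**Figure D3:**
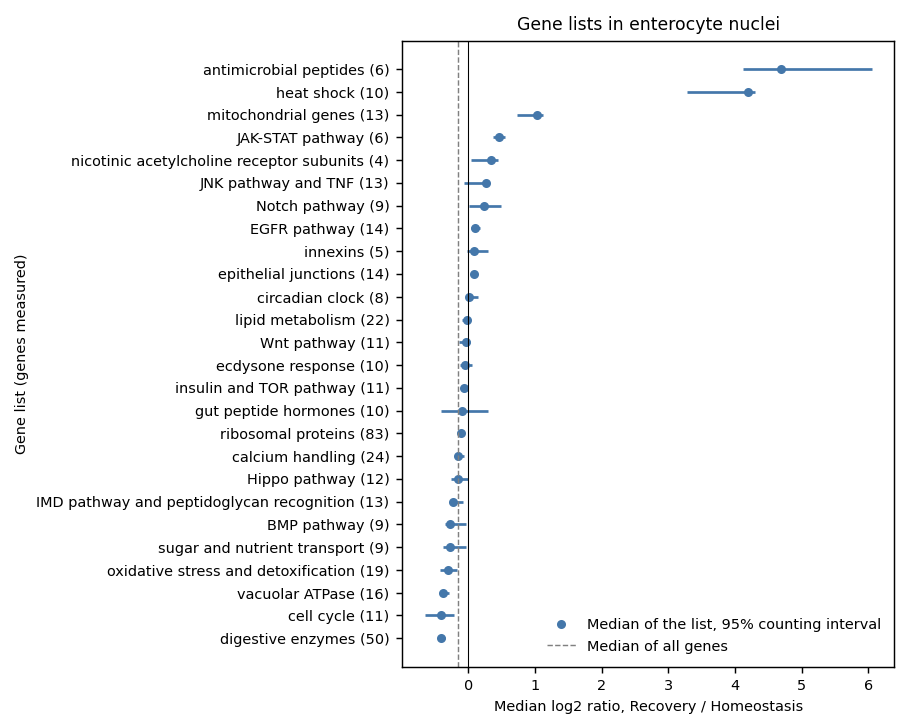
Points give the median log2 ratio (Recovery over Homeostasis, CPM) of each gene list in enterocyte nuclei, lines its 95% counting interval, and the dashed line the median of all genes at -0.16. Antimicrobial peptides and heat shock genes lie above 4 and digestive enzymes at -0.41, while calcium handling, insulin and TOR, ribosomal and Hippo medians, all below 0 here, turn above 0 with DESeq2 size factors, as do the Wnt, ecdysone, lipid and peptide hormone medians, whose intervals hold 0.

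Transcripts of the mitochondrial genome were higher for all 13 measured genes, with a median of 1.04 (0.73 to 1.12; percentile 100). mt:ND2 was 3.52-fold higher (2.74 to 4.57), whereas the abundant mt:CoII was 1.06-fold higher (1.01 to 1.12). Mitochondrial RNA is not nuclear, and its share of all UMIs was 0.254% in Homeostasis and 0.449% in Recovery. Ribosomal protein genes had a median of -0.11 (-0.15 to -0.10; percentile 42.9) that was 0.041 with TMM factors; RpL39 was 1.56-fold higher (1.47 to 1.66) and RpL14 1.501-fold lower (1.40 to 1.60).

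Hormone and nutrient pathways went both ways. Insulin and TOR genes had a median of -0.07 (-0.11 to -0.01; percentile 63.9), which was 0.081 with TMM factors. The insulin receptor InR was 1.56-fold higher (1.52 to 1.61), and ImpL2, a secreted insulin-binding protein that is also a target of ecdysone, 10.7-fold higher (6.20 to 19.7). Ecdysone response genes had a median of -0.05 (-0.13 to 0.05; percentile 71.6), with Eip78C 2.39-fold higher (2.11 to 2.71) and the receptor EcR 1.53-fold lower (1.46 to 1.61). In lipid metabolism, at a median of -0.02 (-0.10 to 0.03; percentile 89.5), the sterol transporter Npc1b was 1.59-fold higher (1.44 to 1.76), while Lsd-1, a lipid droplet protein, and mdy, which makes triglycerides, were 1.83-fold (1.67 to 2.00) and 1.89-fold (1.41 to 2.57) lower. Sugar and nutrient transport had a median of -0.28 (-0.38 to -0.03; percentile 23.4), with the amino acid transporter sbm 1.71-fold higher (1.504 to 1.951) and Glut1 1.57-fold lower (1.32 to 1.87). Peptide hormone transcripts in enterocytes had a median of -0.10 (-0.41 to 0.29; percentile 61.9).

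Other signalling and structural lists also went both ways. Wnt genes had a median of -0.03 (-0.14 to 0.02; percentile 74.1), with the antagonist nkd 1.21-fold higher (1.13 to 1.30) and the receptor fz2 1.37-fold lower (1.32 to 1.43). BMP genes had a median of -0.27 (-0.36 to -0.03; percentile 13.2), with the ligand gbb 1.70-fold lower (1.15 to 2.56) and shn 1.36-fold higher (1.32 to 1.39). Hippo genes had a median of -0.16 (-0.26 to -0.01; percentile 40.4), 0.0058 with DESeq2 size factors, with ft 1.61-fold lower (1.09 to 2.41) and Diap1, an inhibitor of cell death, 1.10-fold higher (1.06 to 1.13). Clock genes had a median of 0.02 (-0.04 to 0.14; percentile 73.5), with cwo 1.27-fold higher (1.24 to 1.29) and tim 1.13-fold lower (1.11 to 1.15). Junction genes had a median of 0.09 (0.05 to 0.12; percentile 82.2) that was -0.13 with the same mix of clusters. The septate junction gene mesh was 1.22-fold higher (1.19 to 1.25) and pyd 1.28-fold (1.23 to 1.33), whereas dlg1 was 1.42-fold lower (1.38 to 1.46) and Gli 1.28-fold lower (1.24 to 1.32), both in 6 of 6 clusters.

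For acetylcholine reception, nAChRalpha7 was the most abundant nicotinic receptor subunit of enterocytes, at 226.3 CPM in Homeostasis and 328.8 CPM in Recovery. It was 1.45-fold higher in Recovery (1.37 to 1.54) and not lower in any of the 6 clusters compared, with 1.78-fold in pEC1 (1.61 to 1.96), 1.74-fold in pEC3 (1.51 to 2.01) and 1.00-fold in pEC2 (0.847 to 1.19). A UMI of nAChRalpha7 was present in 44.1% (42.2 to 46.1) of Homeostasis and 52.8% (50.6 to 55.0) of Recovery enterocyte nuclei. With each nucleus thinned to 899 UMIs, which left out 29 and 16 shallower nuclei, the shares were 16.8% (15.3 to 18.3) and 22.9% (21.04 to 24.81). In nuclei of the cluster annotated cardia, taken as the background, the shares before thinning were 0.373% and 1.20%, at median depths of 1042 and 1036 UMIs against 3610 and 3324.5 in enterocytes. nAChRalpha4 was 1.10-fold higher (0.975 to 1.25), nAChRbeta1 1.60-fold (0.878 to 2.94) on 23 and 26 UMIs, and nAChRalpha3 1.06-fold lower (0.817 to 1.39), so these differences were within counting error. The 4 measured subunits had a median log2 ratio of 0.34 (0.04 to 0.44; percentile 97.7).

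Ace, the acetylcholinesterase that breaks acetylcholine down, was 1.78-fold lower in Recovery enterocytes (1.66 to 1.90), at 306.6 against 172.7 CPM. The lower values lay in pEC3 (1.81-fold, 1.59 to 2.06), aEC1 (1.36-fold, 1.20 to 1.55) and aEC2 (1.39-fold, 1.11 to 1.76), while in pEC1 it was 1.02-fold lower (0.836 to 1.24). With the same mix of clusters it was 1.33-fold lower. ChAT, which makes acetylcholine in neurons, had 4 UMIs in Homeostasis enterocytes and 18 in Recovery, a ratio of 6.37 (2.10 to 25.9). These were the 2 measured genes of acetylcholine synthesis, transport and breakdown. None of the 3 muscarinic receptors reached 20 UMIs in enterocytes.

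**Figure D4:**
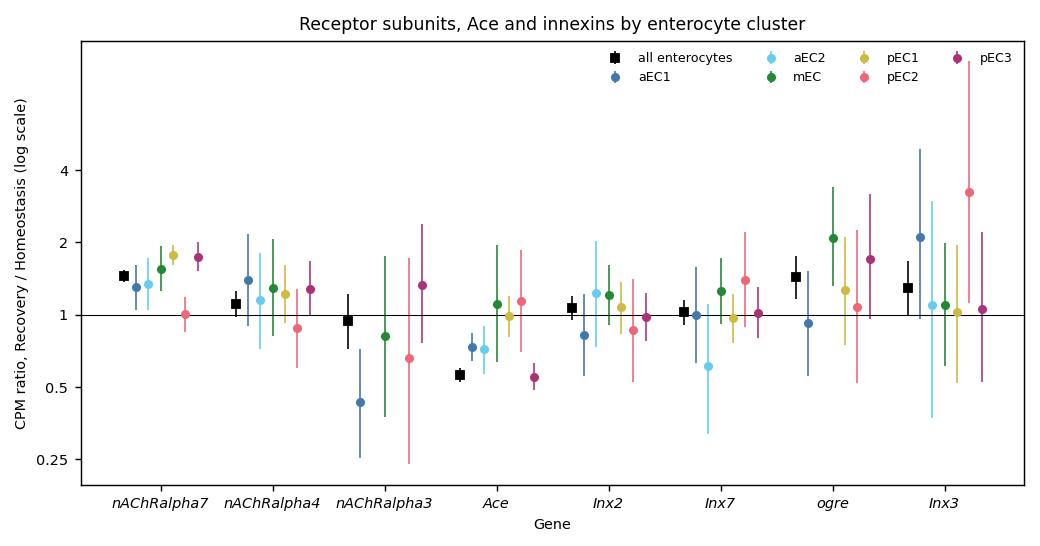
Points give the CPM ratio (Recovery over Homeostasis, log scale) of nicotinic subunits, Ace and innexins in all enterocyte nuclei (squares) and in each of 6 enterocyte clusters (circles), with exact 95% counting intervals; pairs of gene and cluster under 20 UMIs are not drawn. nAChRalpha7 lies at 1.78 in pEC1 and 1.00 in pEC2, and Ace at 0.563 over all enterocytes.

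Innexins, which form the gap junctions of insects, differed little. Of 5 measured in enterocytes 4 were higher, with a median log2 ratio of 0.09 (-0.02 to 0.29; percentile 90.8). Inx2 was 1.06-fold higher (0.949 to 1.19) and Inx7 1.02-fold (0.909 to 1.15), both within counting error, as was shakB at 1.06-fold lower (0.797 to 1.43), whereas Inx3 was 1.30-fold higher (1.00 to 1.68). ogre was 1.43-fold higher (1.17 to 1.75), led by mEC at 2.09-fold (1.32 to 3.41). In ISC/EB, ogre had 5 and 20 UMIs, a ratio of 2.83 (1.03 to 9.65) that was 0.991 without its 5 richest nuclei, and Inx3 was 1.08-fold higher (0.680 to 1.75). Calcium handling genes had a median of -0.15 (-0.20 to -0.07; percentile 43.5), which was 0.00335 with TMM factors, with 9 higher and 15 lower. The calcium-dependent kinase CaMKI was 1.48-fold higher (1.31 to 1.67) and the phospholipase C norpA 1.25-fold (1.17 to 1.34), while the channels Pkd2 and Ca-alpha1D were 1.78-fold (1.30 to 2.47) and 1.97-fold (1.05 to 3.92) lower.

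Among the genes named by size alone in enterocytes, the long non-coding RNA lncRNA:CR34335 was 4.33-fold higher in Recovery (4.28 to 4.37), at 4393 CPM in Homeostasis and 1.90e+04 CPM in Recovery, and it was present in 1976 of 1978 Recovery nuclei. CG43134 was 8.88-fold higher (5.84 to 14). Others rested on few nuclei: apolpp, the apolipoprotein of fat body, was 15.9-fold higher but 1.31-fold (0.569 to 3.02) without its 5 richest nuclei, CG42705 was 13.0-fold higher but 1.63-fold (0.939 to 2.83) without them, and CG42704 8.63-fold higher but at a ratio of 0.812 (0.545 to 1.20). Scp2, a calcium-binding protein gene with 2 and 153 UMIs, 150 of them in 1 nucleus, leads the mEC cluster and is not read as a difference, and the same holds for CG5770 and stl, which lead mEC and the clusters aEC2 and aEC3.

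Genes lower by the same rule were spread over many nuclei. The folds given here are not adjusted for the mix of enterocyte clusters, which differed between the libraries. With the same mix, 24 enterocyte gene ratios (named, receptor, acetylcholine and innexin genes) stayed within their interval and 11 moved. Without aEC3 the counts were again 24 and 11. The ionotropic receptor Ir41a was 2.95-fold lower (2.57 to 3.38), with a UMI in 716 Homeostasis and 227 Recovery nuclei. The cytochrome P450 genes Cyp28d2 and Cyp311a1 were 3.14-fold (2.61 to 3.79) and 2.77-fold (2.26 to 3.42) lower. qvr, a membrane-anchored protein that modulates potassium channels, was 3.98-fold lower (2.82 to 5.75), and Hs6st, which sulfates heparan sulfate, 2.30-fold lower (2.20 to 2.42). The immunoglobulin family gene dpr21 was 2.38-fold lower (2.13 to 2.66) and comm3 2.35-fold lower (2.20 to 2.52). CG12766, CG11241 and CG31041 were 3.38-fold, 2.79-fold and 2.84-fold lower.

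**Figure D5:**
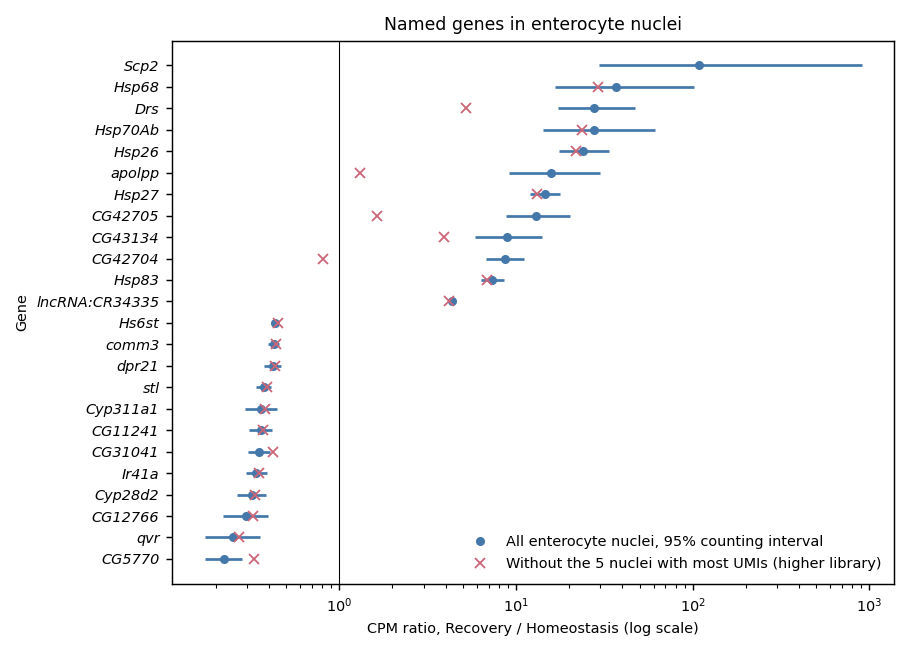
Circles give the CPM ratio (Recovery over Homeostasis, log scale) of the 12 highest and 12 lowest genes in enterocyte nuclei with exact 95% counting intervals, and crosses the ratio without the 5 nuclei that hold most of the gene's UMIs in the library where it is higher (Scp2 keeps no Recovery UMI and has no cross). Hsp26, Hsp27 and Hsp83 differ little between circle and cross, whereas apolpp lies at 15.9 with them and 1.31 without.

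In ISC/EB, whose totals were 173924 and 245746 UMIs, JAK-STAT genes were again on the higher side, with 5 of 5 measured higher and a median log2 ratio of 0.43 (0.10 to 0.80; percentile 96.9). Socs36E was 1.35-fold higher (1.10 to 1.67) and upd3 1.53-fold (0.867 to 2.79). The Notch ligand Dl was 1.37-fold lower (1.08 to 1.73) and the Notch target E(spl)mbeta-HLH 1.89-fold lower (1.42 to 2.52), while klu, a marker of enteroblasts, was 1.17-fold higher (1.00 to 1.37). The Notch list had a median of -0.20 (-0.39 to 0.14, percentile 12.7). The Dl-led sub-cluster held 91 of 239 Homeostasis and 75 of 327 Recovery nuclei of ISC/EB, so the mix of sub-clusters differed and values over ISC/EB include that. Mitochondrial genes had a median of 0.76 (0.41 to 0.98; percentile 100) and ecdysone genes 0.32 (0.05 to 0.46; percentile 97.5), the latter -0.26 among nuclei with at least 1000 UMIs. The 3 measured transport genes were lower, at a median of -0.54 (-0.83 to -0.07; percentile 1.45), with the amino acid transporter path 1.49-fold lower (1.19 to 1.86); the median was 0.086 without the 5 richest nuclei of each gene. Digestive enzymes had a median of -0.17 (-0.29 to 0.01; percentile 4.70).

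The genes named by size in ISC/EB were higher by 3.03-fold for lncRNA:CR34335 (2.79 to 3.30), at the lowest mean of any cluster with 2.86 and 8.95 UMIs per nucleus, 3.64-fold for CG6409 (2.40 to 5.73), 2.83-fold for the immune-induced peptide gene IM33 (1.90 to 4.34) and 3.41-fold for the proton pump subunit VhaAC45 (1.76 to 7.24). pbl, which drives cytokinesis, was 2.64-fold higher (1.58 to 4.65), Rip11, a vesicle transport protein, 2.04-fold (1.52 to 2.78) and Cys, a cystatin, 2.77-fold (1.45 to 5.74). Lower were CG13482 at 2.42-fold (1.82 to 3.25), dpr21 at 2.32-fold (1.53 to 3.55), miple2 at 2.08-fold (1.30 to 3.36), Arc1 at 1.91-fold (1.31 to 2.80) and the tyrosine kinase FER at 1.77-fold (1.44 to 2.18). The histone demethylase lid was 2.83-fold lower (1.56 to 5.29), but its ratio was 1.15 among nuclei with at least 1000 UMIs. Muc68D (3.18-fold higher) and CG7720 (2.98-fold lower) turned direction without their 5 richest nuclei, at ratios of 0.708 and 3.64. The insulin receptor InR was 1.40-fold higher (1.13 to 1.74), the calcium exchanger Calx 1.74-fold (1.28 to 2.37) and mesh 1.93-fold (1.17 to 3.30).

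In the cluster annotated EE, where the median over all genes was -0.14, digestive enzymes were lower for 33 of 37 genes (median -0.53, -0.62 to -0.37; percentile 0) and heat shock genes higher (0.77, 0.19 to 1.56; percentile 99.7). Among receptor subunits, nAChRalpha3 was the most abundant and was 1.14-fold lower (0.935 to 1.39), nAChRalpha4 was 3.95-fold higher (1.79 to 10.3) and nAChRalpha7 2.32-fold higher (1.26 to 4.62). The hormone AstC was 2.62-fold lower (1.84 to 3.73), while Orcokinin was 4.24-fold higher (1.933 to 11.02). The fat body genes Yp1 and Yp3 had 2 and 322 and 1 and 257 UMIs, and 5 Recovery nuclei held 266 and 203 of them. The sub-cluster of EE with a fat body marker among its leading genes held 0 and 7 nuclei. nAChRalpha5, AstA, apolpp and CG42780 are among the leading genes of the cluster and are not read as differences in it. CG42704 (0 and 317 UMIs) was at least 54.1-fold higher but came from 5 nuclei, and Nplp2 (0 and 143) was at least 24.4-fold higher. Lower were spok (69.1-fold, from 2 Homeostasis nuclei), vvl (17.6-fold, likewise 2), CG9682 (16.3-fold, 5 nuclei), whe (8.43-fold), lcs (8.49-fold) and CG18404 (7.23-fold), so these values describe few nuclei of a mixed cluster.

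Over the whole libraries, which mix every cluster at its own share, ribosomal protein genes were higher in 83 of 84 cases (median 0.42, 0.40 to 0.43; percentile 100), while within enterocytes their median was -0.11. Notch genes had a median of 0.48 (0.30 to 0.57; percentile 99.9) and cell cycle genes -0.37 (-0.50 to -0.17; percentile 1.27). The odorant-binding protein gene Obp57a had 0 and 204 UMIs, at least 80.1-fold higher, in 48 Recovery nuclei. Drs was 39.0-fold higher (27.5 to 57.4), in 28 Homeostasis and 214 Recovery nuclei, and Hsp26 and Hsp70Ab were 21.9-fold (16.4 to 29.9) and 27.2-fold (14.1 to 60.4) higher. CG15353 (67.2-fold) and CG42780 (38.2-fold), which lead LFC,Cu,Fe and EE, were 5.05-fold and 4.57-fold higher without their 5 richest nuclei. The genes CG12766, Cyp311a1, Cyp28d2 and Ir41a were 3.88-fold, 3.19-fold, 2.87-fold and 2.81-fold lower, and CG5770 and stl, which lead clusters, 4.48-fold and 2.63-fold.

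In the other clusters the 2 highest genes were often heat shock genes. Hsp27 was 29.8-fold higher in aEC1, 17.2-fold in pEC1, 18.0-fold in pEC2 and 19.3-fold in cardia, and in aEC2 it had 1 and 208 UMIs, a ratio of 425 (75.5 to 1.69e+04). In pEC3, Drs was 41.6-fold higher, 92.2% of its Recovery UMIs lying in 5 nuclei. In mEC, Hs6st was 2.83-fold lower (2.62 to 3.07), AdamTS-A had 0 and 80 UMIs (at least 23.2-fold higher, 8 nuclei) and Cyp6a18 was 16.1-fold lower (4 and 2 nuclei). comm3 was 2.84-fold lower in pEC2 and 2.88-fold lower in pEC3. The transcription factor gene sens-2 and the malic enzyme Men-b were lower in aEC2, with Men-b at 5.61-fold in 47 and 13 nuclei, and Dgp-1 was 7.02-fold lower in cardia in 29 and 14 nuclei. In LFC,Cu,Fe, Drs was 41.2-fold higher in 5 and 101 nuclei. Other genes picked in these clusters, such as bt and slo in aEC1, ct in pEC1, Alp2 in pEC2 and Antp in unknown2, rested on 5 or fewer nuclei in a library or lost their direction without the 5 richest.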

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

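The heat shock tests and the list of genes that went opposite ways in different clusters were chosen after the results were seen, whereas the tests on aEC3 were chosen before their results. The opposite genes were narrowed, after a first look, to the study's receptor and innexin genes and the named enterocyte genes with at least 50 UMIs in a cluster. With 1 library per group, none of the differences between clusters was tested.

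Hsp83 was 24.7-fold higher in Recovery in aEC2 (14.02 to 47.39; 11 and 41 nuclei with a UMI) but had a ratio of 0.567 (0.344 to 0.938) in unknown2. apolpp had a ratio of 43.1 (22.6 to 94.7) in EE, which is not read as a difference because apolpp is a leading gene of EE, and 0.0531 (0.0255 to 0.100) in LFC,Cu,Fe, where 79 Homeostasis UMIs lay in 3 nuclei. comm3 had ratios of 1.66 (1.13 to 2.51) in LFC,Cu,Fe and 0.348 (0.302 to 0.399) in pEC3. nAChRalpha4 had ratios of 3.95 (1.79 to 10.3) in EE and 0.0465 (0.0164 to 0.108) in proEC, where 57 Homeostasis UMIs came from 3 nuclei. stl, a leading gene of aEC2 and aEC3, had ratios of 2.85 (1.54 to 5.62) in mEC and 0.330 (0.276 to 0.393) in pEC3.

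Heat shock genes were far higher in Recovery enterocytes, at a median log2 ratio of 4.19. A handful of nuclei is argued against, since the median was 3.77 without the 5 richest nuclei of each gene, and so is a depth difference, since at 500 UMIs per nucleus an inducible heat shock UMI was 10.3 times as frequent in Recovery enterocytes (7.23% against 0.701%). Free RNA in the droplets would add a like number of UMIs to each nucleus, so after thinning the shallower nuclei would keep at least as large a share. Median depths in Recovery were 3324.5 UMIs in enterocytes, 877 in EE, 1036 in cardia, 743.5 in unknown2 and 693 in ISC/EB. The thinned Recovery shares of EE (6.49%, 4.11 to 9.66), cardia (6.02%, 3.94 to 8.76) and unknown2 (8.40%, 5.21 to 12.7) overlap the 7.23% (6.13 to 8.46) of enterocytes. Those of ISC/EB alone (2.59%, 1.12 to 5.04) and with proEC (1.91%, 0.955 to 3.39) lie below it, which argues against free RNA as the whole source in enterocytes. The shares of EE, cardia and unknown2 also lie above that of ISC/EB with proEC, but EE and cardia overlap ISC/EB alone. In cardia, 13 of 417 Recovery nuclei held 75.7% of the inducible heat shock UMIs. Free RNA as the whole source is thus argued against in these 3 clusters too, less firmly in EE, and stays open in the remaining clusters. Heat stress of whole guts in handling stays open: at least 2 such UMIs were found in 0.693% (0.189 to 1.77) of thinned ISC/EB and proEC nuclei against 3.99% (3.17 to 4.95) of enterocyte nuclei, but nuclei outside the enterocytes also carried a heat shock UMI more often in Recovery (4.35% against 0.32%), and cell types may differ in how they respond to heat. A response to the injury itself is likewise open, and was not tested apart from the handling of 1 pool of guts.

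The cluster aEC3 was nearly absent from Recovery. Low depth is argued against, because among nuclei with at least 5000 UMIs aEC3 was 2.13% (0.923 to 4.15; 8 of 376) in Recovery and 20.2% (124 of 615) in Homeostasis. Set against the Homeostasis cluster profiles without genes that differed over 1.5-fold (4217 genes), 5.01% (4.09 to 6.06) of Recovery enterocyte nuclei fell to aEC3, 99 nuclei of which 55 were annotated aEC1. With all genes kept the share was already 4.35% (3.49 to 5.34), so the excess over the annotated 2.17% of enterocytes came mostly with the projection itself and not with leaving out the differing genes; held-out Homeostasis nuclei gave 18.4%, with 82.4% of aEC3 nuclei found. The projection also errs on held-out Homeostasis nuclei, of which 83.7% kept their cluster, so the excess need not be hidden aEC3 nuclei. The bounds of 4.09% and 6.06% lie below the 18.4% of held-out Homeostasis nuclei. The held-out nuclei came from the library that gave the profiles, so they do not show how well aEC3 nuclei of the other library are found. How much of the gap wrong assignment makes up thus stays open. Of the 10 leading aEC3 genes 8 were lower in the other enterocyte clusters in Recovery, at a median log2 ratio of -0.17. The median over all genes was -0.15 without aEC3, so as a set they barely stood apart. Neither a wrong assignment nor a loss of cells after injury can be excluded.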

How the results depend on the processing

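The alternatives without aEC3, without aEC3 and mEC, without the 5 richest nuclei of a gene, without nuclei rich in heat shock UMIs, without the 5% highest doublet scores, with proEC and for the enteroendocrine sub-cluster were chosen after seeing the data, as were the 6 lists treated as main results (nicotinic subunits, innexins, JAK-STAT, antimicrobial peptides, heat shock, digestive enzymes). Among these lists and the shares, no direction turned: under the alternatives 59 medians and 6 share differences stayed within the interval of the reported value, and 19 and 8 moved. Of gene ratios 648 stayed within that interval, 108 moved and 5 reversed, and of other medians 382, 56 and 16. These counts leave out the setting without called doublets. A reversal is counted only where the interval of the reported value lay off 0 (off 1 for a ratio). For medians it is judged against 0 and not against the median of all genes, which was below 0 in enterocytes with CPM. The cause of a move was not tested unless named.

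The enterocyte share difference was -17.5 points with at least 1000 UMIs per nucleus, -11.1 with rebuilt clusters and -9.42 without aEC3; aEC3 was at -13.7 with at least 1000 UMIs. Rebuilt classes share only part of their nuclei with the annotated ones. The ISC/EB difference was 3.22 with rebuilt clusters and 4.33 with proEC, and the EE difference 0.144 with rebuilt clusters and 0.252 in the marker-led sub-cluster.

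TMM and DESeq2 scaling shift all enterocyte medians up by about the all-gene median: nicotinic subunits to 0.49 and 0.50, JAK-STAT to 0.62 and 0.63, heat shock to 4.35 with either, digestive enzymes to -0.26 and -0.25. The shift reversed calcium handling (0.00335 and 0.011), insulin and TOR (0.081 and 0.089), ribosomal proteins (0.041 and 0.049) and, with DESeq2 only, Hippo (0.0058). The Wnt, ecdysone, lipid and peptide hormone medians, whose intervals held 0, lie above 0 with either scaling too. With the same mix of clusters JAK-STAT was 0.34, digestive enzymes -0.24 and junctions -0.13 (reversed). Without aEC3, digestive enzymes were at -0.30 and junctions at -0.022 (reversed). Without aEC3 and mEC, JAK-STAT was 0.30, antimicrobial peptides 4.11, digestive enzymes -0.31, and junctions (-0.058) and Notch (-0.066) reversed.

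Antimicrobial peptides were at 3.26 without the highest doublet scores and 2.94 with genes of at least 1 UMI. Without the 5 richest nuclei they were at 2.88 and digestive enzymes at -0.27, and EGFR (-0.0135) and Notch (-0.016) reversed, as did transport in ISC/EB (0.086) and the ratios of CG42704 (0.812) in enterocytes and Muc68D (0.708), CG7720 (3.64) and ogre (0.991) in ISC/EB, by the construction of this setting. Heat shock was 2.01 without nuclei of 5 or more heat shock UMIs. In ISC/EB, ecdysone genes were at -0.26 and lid at a ratio of 1.15 with at least 1000 UMIs per nucleus, and ecdysone genes at -0.074 with genes of at least 1 UMI; these nuclei had medians of 673 and 693 UMIs, so the minimum leaves few of them. The innexin median stayed within its interval under every alternative run.

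Leaving out called doublets took out 1 nucleus and so says nothing about stability. Counting every barcode changes nothing here, as 0 barcodes lack an annotation, and the alternative for normalized values does not apply to counts. No paired analysis was possible because each group has 1 library. Depth limits receptor subunits other than nAChRalpha7 and all genes of the small clusters.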

Other observations

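All tests on lncRNA:CR34335, the sub-clusters and the rebuilt heat shock cluster were chosen after the results were seen.

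In the enteroendocrine sub-cluster (29 and 43 nuclei) few nuclei carried each hormone. AstC was 2.52-fold lower in Recovery (1.77 to 3.62; 14 and 13 nuclei) and Tk 1.99-fold lower (1.42 to 2.79; 7 and 13), while Orcokinin was 5.13-fold higher (2.21 to 14.6; 4 and 8). The enteroendocrine transcription factor pros was 1.07-fold higher (0.691 to 1.68; 19 and 25 nuclei) and CCHa2 1.20-fold (0.790 to 1.86; 7 and 12). Among receptor subunits, nAChRalpha4 had 3 and 28 UMIs, a ratio of 5.22 (1.61 to 26.8), in 2 and 17 nuclei. The other measured subunit, nAChRalpha5, went the other way with 38 and 22 UMIs, a ratio of 0.324 (0.183 to 0.562), in 9 and 7 nuclei. It is a leading gene of EE and is not read as a difference.

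Within proEC, 1 sub-cluster led by genes that include the progenitor marker esg held 16 Homeostasis and 88 Recovery nuclei, and 1 led by genes that include pbl, upd3 and Sox21a held 14 and 53. The others held 49 and 44, 21 and 26, 17 and 16, and 13 and 41, so the mix of sub-clusters differed between the libraries and values over proEC include that. The leading genes of the last of these include yl, gnu, dhd and CycB. The dhd UMIs and nearly all CycB UMIs of proEC came from a few Homeostasis nuclei, as given above, so these genes do not describe its Recovery nuclei. The matrix protease Mmp2 was 6.74-fold higher in proEC (2.50 to 25.5; 3 and 24 nuclei), JNK genes had a median log2 ratio of 0.46 (0.23 to 0.75; percentile 99.1) and junction genes 0.35 (0.17 to 0.61; percentile 99.5). Ribosomal protein genes were lower there in 76 of 82 cases (-0.48, -0.56 to -0.43), and Marf1 (163 and 2 UMIs) was 184-fold lower (50.3 to 1536), all its Homeostasis UMIs lying in 5 nuclei. In enterocyte clusters, vacuolar ATPase genes were lower in 16 of 16 cases in pEC1 (-0.52, -0.59 to -0.33; percentile 0) and 15 of 16 in mEC (-0.45, -0.53 to -0.32; percentile 0.02), and junction genes in 13 of 14 in aEC2 (-0.34, -0.43 to -0.19; percentile 0.05). A rebuilt cluster with Vha100-4 and lab among its leading genes, 83.4% annotated mEC, held 137 Homeostasis and 62 Recovery nuclei. Another, 45.4% annotated mEC, held 127 and 351. Others most often annotated mEC held 175 and 102, and 48 and 37. The mix of nuclei within mEC may thus differ between the libraries, and values over mEC would include that. In unknown1, Pino and the glutathione transferase GstT4 were 2.59-fold (2.11 to 3.19) and 2.86-fold (2.01 to 4.14) higher.

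Clustering of all nuclei without the authors' annotation gave a cluster of 119 nuclei led by Hsp26, Hsp23 and Hsp27, with 0 nuclei from Homeostasis; 28.6% of it was annotated pEC3.

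lncRNA:CR34335 was higher in Recovery in every cluster compared, from 2.81-fold in proEC (2.56 to 3.09) to 4.37-fold in mEC (4.19 to 4.56). Free RNA in the droplets is argued against as the source in clusters over 2 times the lowest, as the mean per Recovery nucleus ranged from 8.95 UMIs in ISC/EB to 133 in aEC3, a ratio of 14.9. The lowest clusters, ISC/EB, proEC (12.4) and unknown2 (13.0), are those not over 2 times the lowest mean. Their means lay within a ratio of 1.45, but this likeness follows from how they were picked and is no evidence of a common background. A common background that was higher in Recovery may account for them, so free RNA stays open there. A few genes taking most of the counts is argued against too. The 20 most abundant genes held 9.16% of all UMIs in Homeostasis and 10.4% in Recovery. The enterocyte ratio of 4.39 with the 20 most abundant genes left out of the total adds nothing, since so small a part could hardly move it. A difference in how the libraries were made, which no label records, and an effect of the injury both stay open and may not be separable with 1 library per group.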
